A study of Mus musculus with 12 samples.

How the data were processed

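RNA from 6 clones of MH-S, a mouse alveolar macrophage cell line, was measured on 12 Affymetrix Mouse Gene 2.1 ST arrays, 1 array per clone and condition. The labels place clones 7, 29 and 75 in a group with low activity of the interleukin-4 receptor alpha chain (IL-4Ra) and clones 69, 73 and 83 in a group with high activity. How that activity was measured, and whether it means surface level, allele usage or signalling, is not given in the sources used here. Each clone was kept unstimulated or was given lipopolysaccharide (LPS) of Salmonella Minnesota R595 at 0.2 µg/ml for 16 h, per the labels' protocols. This gave 4 groups of 3 arrays. Each clone gave 1 unstimulated and 1 LPS array, so the clone is the replicate. The main fit has no term for the clone, and its p-values measure the spread of arrays between clones of the same line. For LPS changes and their differences this spread includes baseline differences between clones, not only differences in response. A fit that leaves out 1 array keeps the other array of that clone without its pair. Its LPS changes therefore include baseline differences between clones as well. The labels give no batch, slide or scan date.

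The deposited log2 values were made by the authors with Affymetrix Expression Console, per the submitters' processing notes and the file headers; its version is not given in the sources used here. The method was RMA, which corrects the probe intensities for background, brings all arrays to the same distribution by quantile normalization and summarises the probes of each transcript cluster by median polish. The workbook's annotation is NetAffx build 34 on the mouse assembly mm10, and all coordinates are given as that annotation gives them. The workbook holds 41345 features. The series matrix holds 41155 of them, and the largest difference between both tables was 0. The workbook also holds the authors' deposited fold change of LPS against unstimulated arrays over all clones, a score written as minus the inverse where the ratio was under 1, with the p-value and q-value of an unpaired t-test on untransformed values, per the file headers. Those columns were used only where the authors' deposited table is named. There were 0 columns of values per sample that went unused.

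Of the 41345 features, 33793 belong to the main category and 29294 of these carry a gene symbol. Control, rescue and ribosomal features were left out of the gene tests. Gene identifiers of 25154 features matched a RefSeq gene table of assembly GRCm38.p6 (used for names only), and 1885 symbols were updated through it; the other features keep the file's symbol. Where a gene had several features (1370 genes), the one with the highest mean over all arrays stood for it, which left 27296 genes. The annotation marks the probes of 1971 of these genes as able to bind transcripts of other genes. Histone, guanylate-binding protein, Ifit1bl and Trim30 genes belong to families of near-identical copies, and their single values are uncertain for that reason.

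Tests were made on the deposited log2 values with limma 3.58.1 (lmFit and eBayes, default settings) in R 4.3.3, with version 1.17.8 of data.table and 1.5.0 of statmod. A single fit of the 4 groups over all 12 arrays, without a term for the clone, gave 6 comparisons. These were LPS against unstimulated over all clones, in the low clones and in the high clones, high against low clones without and with LPS, and the difference of the LPS responses between high and low clones. The seventh compared high with low clones on the mean of each clone's arrays (6 values). All tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 27296 genes. Errors beside log2 changes are standard errors of the fit, and errors beside group levels are SDs over 3 clones. The number of arrays limits the precision: in simulated data of the same size, a log2 change of 1 was recovered for 95.5% of changed genes in the LPS comparison over all clones, 77.6% in low clones, 80.6% in high clones, 79.1% and 83.6% for high against low clones without and with LPS, 49.3% for the difference of responses and 89.6% for the clone means. A log2 change of 0.5 was recovered for 61.2%, 29.9%, 19.4%, 25.4%, 31.3%, 7.46% and 32.8%, in the same order. The simulated arrays carried independent noise, without deviations shared by both arrays of a clone. Where a clone's arrays deviate together, the shares given for the clone means are too high.

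The labels name the clone of each array, so both arrays of a clone are paired by the design. Deviations of a clone's unstimulated and LPS arrays from their group means correlated at 0.226 for clone 7, 0.195 for clone 29, 0.1 for clone 75, 0.402 for clone 69, 0.408 for clone 73 and 0.415 for clone 83; for clone 75 another clone's array correlated slightly better (0.101). Fits with the clone as a fixed block (LPS comparisons and the difference of responses) or as a random block (high against low clones) are given beside a result where they change its call or move a count by more than 1.5 times.

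Lists of 26 gene groups were tested with limma's camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists within each comparison, which made 182 tests. They were IL-4 receptor complex and signalling, IL-4-induced genes, TLR4 pathway, inflammatory cytokines, chemokines, NF-kB feedback and regulators, interferon-stimulated genes, antimicrobial and inflammatory effectors, antigen presentation and co-stimulation, alveolar macrophage identity, pan-macrophage identity, monocyte and dendritic cell markers, neutrophil and mast cell markers, lymphocyte markers, fibroblast and epithelial markers, cell cycle, cholesterol synthesis and uptake, cholesterol efflux, glycolysis, mitochondrial respiration, NRF2 and oxidative stress, unfolded protein and integrated stress response, lysosome, scavenger and phagocytic receptors, DNA methylation and histone modifiers, and cytosolic ribosomal proteins. The cholesterol efflux list also holds other genes of lipid handling, and the glycolysis list also holds genes of hypoxia. Beside each list stands the number of members called over all genes and, in those words, adjusted over the list alone. A result that ended when camera estimated the correlation from the data has that adjusted p beside it.

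The groups, the tests, the gene lists, the alternatives listed below, except the last group, and the rule for the named genes were fixed before the data were examined. The rule took, among called genes, the 10 largest rises and the 10 largest falls of a comparison (5 and 5 for low clones, high clones and the difference of responses) that went the same way in every clone or whose groups did not overlap, leaving out gene-model names and small RNAs. It added Il4ra in every comparison, a fixed set of LPS and IL-4 genes (Tlr4, Tnf, Il6, Il1b, Nos2, Arg1, Chil3, Stat6, Il13ra1, Il2rg and Socs1), and up to 4 members of each list described. The alternatives were the series matrix table, quantile normalization applied again, median centring, a filter on dim genes (above the 40th percentile of the mean), the mean of a gene's features, all features, a variance trend with robust estimation, array weights, a log2 change of at least 1, a fit of the compared groups alone, the clone block and leaving out each array, and for lists an estimated correlation, ranks, the block and the dim filter. The methods' t-test, leaving out both arrays of clone 75, leaving out chromosomes 14 and 15, and, for the lists, leaving out single arrays and other scalings were chosen after seeing the data. Any gene with a smaller change fails the alternative of a log2 change of at least 1 by construction. The numbers of alternatives passed are lower for such genes for that reason. The test code was checked on simulated arrays before it was run.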

Results

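Gene expression was measured in 6 clones of MH-S, an alveolar macrophage line from mouse, with 1 array per clone without stimulation and 1 array after 16 h with LPS, the bacterial cell wall component sensed by TLR4. Clones 7, 29 and 75 carry the label of low IL-4Ra activity and clones 69, 73 and 83 that of high IL-4Ra activity; IL-4Ra is the chain shared by the receptors for IL-4 and IL-13. Each of the 4 groups held 3 arrays. The comparisons asked what LPS changed in all clones and in each phenotype, how high and low clones differed in each condition, and whether their LPS responses differed. The median log2 level of the arrays lay between 4.42 and 4.46, arrays of a group correlated on average at 0.992 to 0.994 across features, and the contrast of exon over intron control features (area under the curve) lay between 0.904 and 0.915. The SD of the values was lowest in the LPS array of clone 75 (2.46) and otherwise between 2.50 and 2.54. The first principal component, with 38.8% of the variance, separated LPS from unstimulated arrays, and the second, with 14.8%, separated high from low clones.

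Il4ra, the gene of the receptor chain that names the phenotype (chromosome 7, 125552271 to 125579474, mm10), showed no detectable difference in transcript level between the phenotypes. Unstimulated, its log2 level was 7.61 ± 0.58 in low clones and 7.42 ± 0.25 in high clones (SD, n = 3 each), a difference of −0.19 ± 0.29 with adjusted p = 0.903. With LPS the levels were 8.35 ± 0.52 and 8.22 ± 0.33, a difference of −0.13 ± 0.29 with adjusted p = 0.927. Clone 29, a low clone, had the highest level in both conditions (8.24 and 8.87), and clone 75, also low, had the lowest (7.11 and 7.83). The SE of 0.29 leaves room for a difference of either sign, and the sign turned to positive without clone 29 (0.12 unstimulated, 0.13 with LPS) and, with LPS, without clone 83 (0.05). Il2rg, the common gamma chain that pairs with IL-4Ra in the type I receptor (X chromosome, 101264378 to 101268255), was 2.60 ± 0.84 log2 higher in unstimulated high clones and 1.56 ± 0.84 higher with LPS, with a wide spread (unstimulated 6.04, 4.91 and 4.69 in clones 7, 29 and 75 against 7.33, 6.16 and 9.95 in clones 69, 73 and 83). Neither difference passed (adjusted p = 0.224 and 0.557). Without clone 83 they were 1.53 and 0.68.

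LPS raised inflammatory genes of macrophages in every clone. The largest rises over the 6 clones were those of the interleukin-1 genes Il1a (log2 change 7.61 ± 0.28, 195-fold, adjusted p = 8.21e-09; chromosome 2, 129299610 to 129309972) and Il1b (7.03 ± 0.20, 131-fold, adjusted p = 7.45e-10; chromosome 2, 129364570 to 129371139). Nos2, the inducible nitric oxide synthase, rose by 5.90 ± 0.22, Cybb, a subunit of the phagocyte NADPH oxidase, by 5.82 ± 0.33, and the cytokine Il6 by 5.53 ± 0.42. The acute phase gene Saa3 (4.49), the guanylate-binding protein Gbp2 (4.33), Acod1, which makes itaconate (4.06), the complement factor Cfb (3.92) and Igsf6 (3.84) followed. The largest falls were those of Rnase4 (−2.88 ± 0.20), Ccl24, an eotaxin typical of IL-4-treated macrophages (−2.74 ± 0.18, adjusted p = 8.36e-07), the protease inhibitor Serpinb1a (−2.61 ± 0.47, adjusted p = 0.00218), the transcription factor Maf (−2.27 ± 0.30), Tmem158 (−1.97), the proton pump subunit Atp6v0d2 (−1.97), Rasgrp3 (−1.94), Pramel19 (−1.93, probes shared with other genes), Gpr157 (−1.89) and St6gal1 (−1.86).

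**Figure D1:**
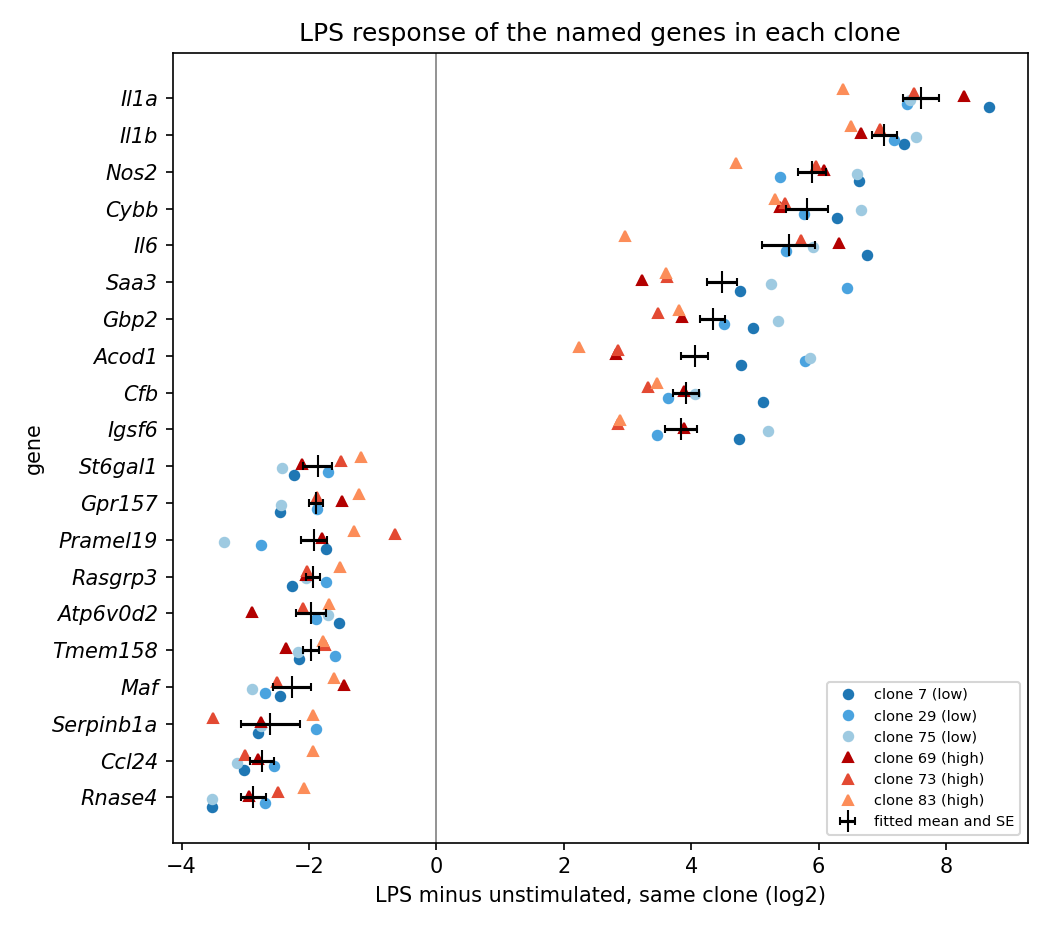
Log2 change with LPS of the 10 genes with the largest rise and the 10 with the largest fall over all clones. Each point is a clone (LPS minus unstimulated array, coloured by phenotype), and black bars show the mean over the 6 clones. The length of the bars is the standard error of the fit without a term for the clone, not that of the 6 points. Il1a rose by 7.61 and Rnase4 fell by 2.88 on average.

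Over all clones 1561 genes rose and 1834 fell, 294 and 151 of them by at least 1 on the log2 scale. With the clone as a block the counts were 1955 and 2407. In the authors' deposited table, 1291 features were higher and 1532 lower at a q-value under 0.05 among 41345. Of its calls among the features tested here, 1035 of 1159 higher and 1232 of 1344 lower were also called by limma.

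Several genes of the LPS and IL-4 pathways responded. Tnf rose by 2.05 ± 0.08 (adjusted p = 8.54e-09) and the LPS receptor gene Tlr4 fell by 0.65 ± 0.10 (adjusted p = 0.000679). Socs1, a feedback inhibitor of cytokine receptors, rose by 0.49 ± 0.09 (adjusted p = 0.00238), and Stat6, the transcription factor activated by the IL-4 receptor, fell by 0.40 ± 0.09 (adjusted p = 0.00786). Il4ra rose by 0.76 ± 0.21 (adjusted p = 0.0284), with a higher level on the LPS array in 6 of 6 clones. With the clone as a block its adjusted p was 0.000103, and over all alternatives it ranged from 0.000103 to 0.106 and passed in 12 of 23. Among the 23 is a log2 change of at least 1, which a change of 0.76 fails by construction. Il4ra did not pass when the unstimulated array of clone 7 (0.0645), 75 (0.0705), 73 (0.0601) or 83 (0.0654), or the LPS array of clone 7 (0.0549), 29 (0.0656), 69 (0.0715) or 73 (0.0602), was left out. Those fits have no term for the clone and break a pair, so baseline differences between clones enter them. Within single clones Il4ra rose by 0.63 to 0.92. Il2rg (1.27 ± 0.60, adjusted p = 0.217) and Il13ra1 (0.25 ± 0.10, adjusted p = 0.128) did not pass without the block and passed with it (0.000161 and 0.0283). The change of Il2rg was 0.84 without the LPS array of clone 83, and without the unstimulated array of that clone it passed (1.81, adjusted p = 0.0253). Both fits break a pair in the same way. Within single clones Il2rg rose by 0.36 to 2.08. Arg1 (0.06 ± 0.09, adjusted p = 0.787) and Chil3 (0.15 ± 0.16, adjusted p = 0.652), classical IL-4 targets, did not pass.

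In the list tests over all clones 8 lists shifted upward, and 5 of them also passed with an estimated correlation. All 40 measured interferon-stimulated genes rose, among them Zbp1 (3.69), Gbp5 (3.36) and the chemokine Cxcl10 (3.27), also adjusted over the list alone (camera adjusted p = 4.71e-48). Of 28 NF-kB feedback genes and regulators 21 rose (25 adjusted over the list alone, adjusted p = 4.59e-31), with Irak3 (2.37), Traf1 (2.33) and the RNase Zc3h12a (2.06) in front. Of 36 antimicrobial and inflammatory effectors 26 rose and 1 fell (the same counts adjusted over the list alone, adjusted p = 1.45e-29), led by Nos2, Cybb, Saa3 and Acod1. Of 26 inflammatory cytokines 14 rose and 1 fell, the same adjusted over the list alone (adjusted p = 5.16e-12), with Csf3 (2.74) after Il1a, Il1b and Il6. Of 24 chemokines 14 rose and 1 fell (16 and 2 adjusted over the list alone, adjusted p = 8.15e-10), with Cxcl2 (3.84) and Cxcl11 (3.83) against the fall of Ccl24. These 5 lists also passed with an estimated correlation, though with much larger adjusted p. Those were 0.0385 for interferon-stimulated genes and for chemokines, 0.00679 for NF-kB genes and 0.0288 for effectors and for cytokines. Antigen presentation and co-stimulation rose in 14 of 22 members (15 adjusted over the list alone, adjusted p = 6.27e-18), such as Cd40 (3.50), Icosl (2.00) and the peptide transporter Tap1 (1.44), with adjusted p = 0.0537 with an estimated correlation. The NRF2 and oxidative stress list shifted upward with 7 of 22 members higher and 2 lower (12 and 3 adjusted over the list alone, adjusted p = 0.000393), with the cystine transporter Slc7a11 (2.08), Sod2 (1.50) and Ftl1 (−0.49) among them. Its adjusted p was 0.0537 with an estimated correlation. The unfolded protein and integrated stress response list shifted upward with 9 of 22 members higher and 2 lower (11 and 3 adjusted over the list alone, adjusted p = 4.84e-05), with Ddit3 (1.11) and Trib3 (1.03), both of the integrated stress response, in front. Its adjusted p was 0.154 with an estimated correlation.

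The list tests over all clones found 4 lists shifted downward, 0 of which passed with an estimated correlation. Of 24 genes of cholesterol synthesis and uptake 18 fell and 0 rose (22 fell adjusted over the list alone, adjusted p = 5.82e-17), including Cyp51 (−1.10) and Hmgcs1 (−1.10). The list had adjusted p = 0.06 with an estimated correlation. The lysosome list shifted downward with 12 of 30 members lower and 1 higher (20 and 2 adjusted over the list alone, adjusted p = 1.39e-08), for example Galc (−0.75), Hexa (−0.53) and Atp6v1a (−0.53), with adjusted p = 0.127 with an estimated correlation. Pan-macrophage identity genes shifted downward with 10 of 24 lower and 2 higher, the same adjusted over the list alone (adjusted p = 0.00106), with the factor Maf and the complement genes C1qc (−1.30) and C1qa (−1.06). The list had adjusted p = 0.0702 with an estimated correlation. Of 30 mitochondrial respiration genes 4 fell (6 adjusted over the list alone, adjusted p = 0.000107), namely Idh2 (−0.60), Sdha (−0.33), Ogdh (−0.32) and Ndufv1 (−0.28), with adjusted p = 0.419 with an estimated correlation.

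The other 14 lists did not pass over all clones, although single members did. IL-4 receptor complex and signalling had 4 of 22 genes higher and 1 lower (5 and 3 adjusted over the list alone, adjusted p = 0.22), with the kinases Jak2 (1.58) and Tyk2 (0.80) among the former. IL-4-induced genes had 6 higher and 6 lower of 38 (9 and 7 adjusted over the list alone, adjusted p = 0.478), with Slc7a2 (2.14) and Ch25h (1.72) against Ccl24 and Pparg (−1.33). The TLR4 pathway had 4 higher and 3 lower of 23 (4 and 4 adjusted over the list alone, adjusted p = 0.307), with Ikbke (1.99) in front. Alveolar macrophage identity had 3 higher and 7 lower of 31 (4 and 7 adjusted over the list alone, adjusted p = 0.292), the latter including Pparg, its main transcription factor, and Mertk (−0.95). Cell cycle had 4 higher and 9 lower of 39 (4 and 10 adjusted over the list alone, adjusted p = 0.141), with Ccnd1 (−1.28), the CDK inhibitor Cdkn2c (−0.89) and Cdc6 (0.73). Cholesterol efflux and lipid handling had 1 higher and 5 lower of 19 (2 and 7 adjusted over the list alone, adjusted p = 0.138). Among those called were Mylip (−0.54) and Cd36 (−0.50). Glycolysis and hypoxia had 2 higher and 3 lower of 23 (2 and 4 adjusted over the list alone, adjusted p = 0.638). Among those called were Vegfa (0.62), Hk2 (0.61) and Pdk1 (−0.46). Scavenger and phagocytic receptors had 3 higher and 6 lower of 26 (the same adjusted over the list alone, adjusted p = 0.335), with Siglec1 (2.17) and Fcgr3 (−1.03). DNA methylation and histone modifiers had 5 higher and 4 lower of 36 (6 and 4 adjusted over the list alone, adjusted p = 0.316), with Tet2 (1.19), Hdac5 (−0.87) and Dnmt3a (−0.66). Cytosolic ribosomal proteins had 4 of 28 higher by both adjustments (adjusted p = 0.0719), with Rps15 (0.44) and Rpl7 (0.41). Their list passed on ranks (0.0429), without the unstimulated array of clone 75 (0.0225) or 83 (0.0303), without the LPS array of clone 75 (0.0122) or 69 (0.0354) and without both arrays of clone 75 (0.00258). Among markers of other cell types, monocyte and dendritic cell markers had 1 of 20 higher (Bst2, 1.96, adjusted p = 0.356), neutrophil and mast cell markers 2 of 20 (S100a8, 1.00, and Camp, 0.89, adjusted p = 0.155), lymphocyte markers 0 of 21 (adjusted p = 0.644), and fibroblast and epithelial markers 3 of 24 (Dcn, 1.45, Acta2, 0.92, and Fbn1, 0.38, adjusted p = 0.117). Without the LPS array of clone 29 the cell cycle list (0.0243) and fibroblast and epithelial markers (0.0487) passed. The change of Dcn was 2.79, 0.77 and 4.27 in clones 7, 29 and 75 and 0.71, 0.21 and −0.05 in clones 69, 73 and 83. Without both arrays of clone 75 neither Dcn (1.03) nor Fbn1 (0.33) was called.

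In the low clones taken alone, 981 genes rose and 1128 fell with LPS. Il1a (7.83 ± 0.40), Il1b (7.35 ± 0.28), Cybb (6.24 ± 0.47), Nos2 (6.21 ± 0.31) and Il6 (6.05 ± 0.59) rose most, and Rnase4 (−3.25 ± 0.28), Ccl24 (−2.90), Maf (−2.68), Pramel19 (−2.61) and Serpinb1a (−2.48) fell most. Tnf rose by 2.41, Socs1 by 0.66 (adjusted p = 0.00533), and Tlr4 fell by 0.71 (adjusted p = 0.00646). The blocked counts were 1302 and 1654. With the block, Il4ra (0.73, adjusted p = 0.175 without and 0.00156 with it), Il2rg (1.79, 0.264 and 0.000291) and Stat6 (−0.40, 0.0669 and 0.0241) passed. The change of Il4ra was 0.48 without the unstimulated array of clone 75 and 0.47 without the LPS array of clone 29. These fits leave an array without its pair, so baseline differences between clones enter the change. Within clones 7, 29 and 75 Il4ra rose by 0.85, 0.63 and 0.72. Leaving out the unstimulated array of clone 75 lowered the counts to 629 and 738, leaving out that of clone 29 lowered the falls to 679, and without both arrays of clone 75 the counts were 519 and 519. The 14 lists that passed included the 12 of the comparison over all clones in the same directions, with 37 of 40 interferon-stimulated genes called. Cytokines, chemokines, NF-kB genes, effectors, interferon-stimulated genes and antigen presentation kept their result with an estimated correlation, with adjusted p of 0.00622 to 0.0482. Cholesterol synthesis (adjusted p = 0.0686 with an estimated correlation), pan-macrophage identity (0.0686), lysosome (0.171), mitochondrial respiration (0.326), NRF2 (0.0703) and the stress response list (0.101) did not. The cell cycle list shifted downward with 6 of 39 genes lower, such as Ccnd1 (−1.37), and 1 higher (adjusted p = 0.0115, and 0.326 with an estimated correlation). It did not pass without the LPS array of clone 75 (0.0871), without both arrays of that clone (0.0812) or with dim genes left out (0.0523). Fibroblast and epithelial markers shifted upward (adjusted p = 0.0162, and 0.0686 with an estimated correlation) through Dcn (2.61), Acta2 (1.01) and Fbn1 (0.59), with 3 of 24 called, and did not pass with dim genes left out (0.0735). Dcn, a matrix proteoglycan of fibroblasts, stood at 6.20, 4.22 and 7.50 on the LPS arrays of clones 7, 29 and 75.

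In the high clones taken alone, 497 genes rose and 562 fell. Il1a (7.39 ± 0.40), Il1b (6.71 ± 0.28), Nos2 (5.58 ± 0.31), Cybb (5.40 ± 0.47) and Il6 (5.0 ± 0.59) rose most, and Serpinb1a (−2.73 ± 0.66, adjusted p = 0.0375, but −1.79 and not called without the LPS array of clone 73), Ccl24 (−2.58), Rnase4 (−2.50), Atp6v0d2 (−2.22) and Tmem158 (−1.96) fell most. Tnf rose by 1.69 and Tlr4 fell by 0.58 (adjusted p = 0.0373). With the block the counts were 831 and 989. Il4ra (0.79, adjusted p = 0.196 without and 0.00188 with it), Il2rg (0.75, 0.782 and 0.0366) and Stat6 (−0.39, 0.112 and 0.0377) then passed, whereas Acta2 (0.82, 0.049 and 0.0919) did not. The sign of Il2rg turned without the unstimulated array of clone 73 (−0.08) or the LPS array of clone 83 (−0.12). Those fits leave an array without its pair, so baseline differences between clones enter the change. Within clones 69, 73 and 83 Il2rg rose by 0.68, 1.21 and 0.36. In a fit of the 6 arrays alone the counts were 293 and 287. Leaving out the LPS array of clone 69 gave 284 and 305, that of clone 73 gave 320 and 342, and without the unstimulated array of clone 73 the falls numbered 369. The 13 lists that passed again included those 12. Of the interferon-stimulated genes 24 of 40 were called (36 adjusted over the list alone, adjusted p = 1.5e-38, and 0.0671 with an estimated correlation). NF-kB genes, cytokines and effectors kept their result with an estimated correlation, with adjusted p of at most 0.0262. Chemokines, antigen presentation and cholesterol synthesis (adjusted p = 0.091 each with an estimated correlation), pan-macrophage identity (0.0934), NRF2 (0.0671), the stress response list (0.351) and lysosome (0.138) did not. Mitochondrial respiration shifted downward (adjusted p = 0.0469, and 0.625 with an estimated correlation) and failed without the unstimulated array of clone 69 (0.0517) or 83 (0.487) or the LPS array of clone 69 (0.211) or 73 (0.234), with dim genes left out (0.0858) and after median centring (0.0548). Cytosolic ribosomal proteins shifted upward with 0 of 28 called (adjusted p = 0.0378, and 0.429 with an estimated correlation) and passed in 3 of 6 fits that left out an array, but not with dim genes left out (0.0873). On ranks the stress response list did not pass (0.0559). Alveolar macrophage identity passed only with the block, downward (adjusted p = 0.115 without and 0.03 with it).

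Low and high clones shared many of their LPS-responsive genes. Across the 3395 genes called over all clones, the changes in high and low clones correlated at r = 0.935 and 99.8% had the same sign; genes are not independent, and these were chosen on the mean of both changes. Called in both phenotypes were 412 rises and 455 falls, against 17.9 and 23.2 for independent lists. The arrays of both comparisons are separate, but each gene's residual spread is that of the single fit in both. A gene with a small spread is more easily called in both, so unrelated lists could share more than 17.9 and 23.2. The median absolute change of the 3395 genes was 0.54 in low clones and 0.44 in high clones.

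**Figure D2:**
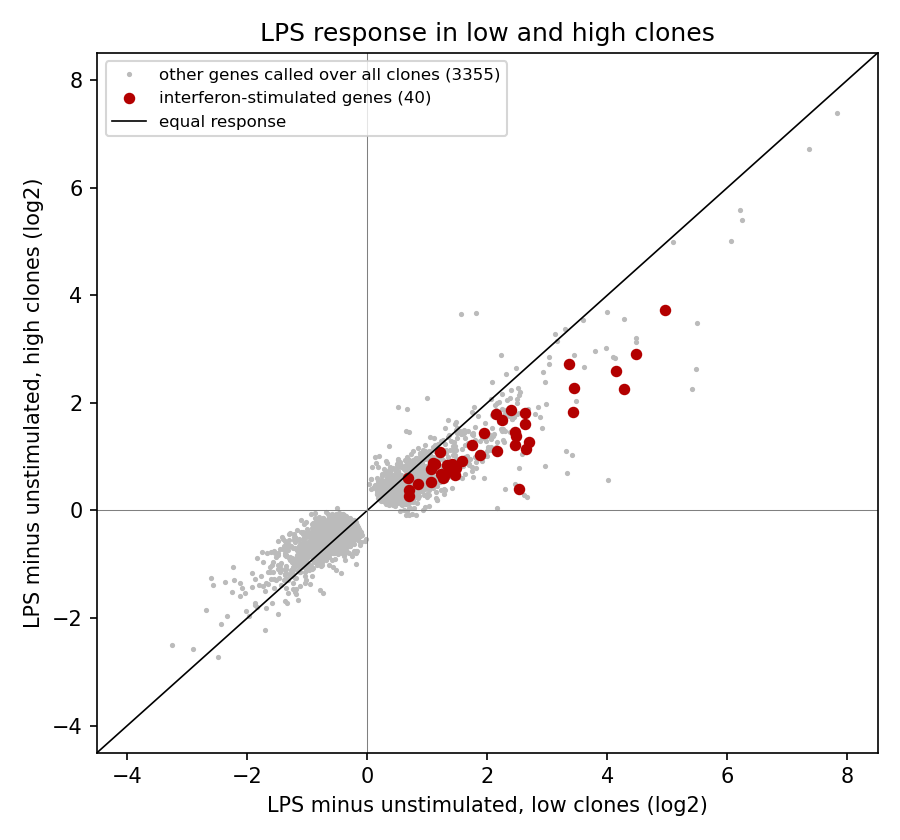
Log2 change with LPS in high clones (vertical axis) against low clones (horizontal axis), each the mean of 3 clones, for the 3395 genes called over all clones, with the interferon-stimulated genes marked; the line marks equal change. The interferon-stimulated genes lie below the line, with a median LPS change per clone of 1.75 to 2.00 in low clones and 1.01 to 1.22 in high clones.

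Where the responses differed, interferon-stimulated genes rose less in the high clones. The difference of responses was negative for all 40 measured members, with a median of −0.65 (camera adjusted p = 2.62e-24, and 0.212 with an estimated correlation), and the median LPS change of the list was 1.75, 2.00 and 1.93 in clones 7, 29 and 75 against 1.01, 1.05 and 1.22 in clones 69, 73 and 83. None of the 40 genes was called over all genes (0), and 14 were lower adjusted over the list alone. Called genes were 3 lower and 0 higher (limma; 1290 genes had an unadjusted p under 0.05). They were Trim30c, of the Trim30 family (−1.97 ± 0.22, chromosome 7, 104382065 to 104400837), and LOC630751 (−2.42 ± 0.24, chromosome 18, 60439295 to 60443848, probes shared with other genes) and Gm12250 (−2.12 ± 0.23, chromosome 11, 58183843 to 58190198), all with adjusted p = 0.00573. The last 2 are gene-model names outside the naming rule and were chosen after their values were seen. Their log2 changes had the same sign in all alternatives, and the adjusted p of Trim30c ranged from 0.00174 to 0.0817 and passed in 21 of 22. With the clone as a block 14 genes were lower and 1 higher, among them Cxcl11 (−3.14), Acod1 (−2.84), Ifit1 (−1.59), Rsad2 (−1.49) and Ifih1 (−1.26), with blocked adjusted p of 0.00322 to 0.0498 over the 15. These were also chosen after their values were seen. Acod1, Rsad2 and Ifit1 were called higher in unstimulated high clones, so their smaller rise includes a difference in baseline. Without the unstimulated array of clone 7 or 83 there were 5 lower, and without the LPS array of clone 83 there were 5 lower and 1 higher. Il4ra (0.06 ± 0.42, adjusted p = 0.997) did not pass, and its sign turned without the unstimulated array of clone 29 (−0.25) or 83 (−0.05), without the LPS array of clone 75 (−0.20) or 69 (−0.08), and with array weights (−0.04). Where an array was left out, here and for Il2rg, a pair was broken, so baseline differences between clones enter the value. Il2rg (−1.04 ± 1.19, adjusted p = 0.983) did not pass and was 0.03 without the unstimulated array of clone 83; the other fixed genes had adjusted p of 0.673 to 0.997.

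For the difference of responses 8 further lists passed at the fixed inter-gene correlation and 0 with an estimated one, each with 0 members called over all genes. Downward here means a lower LPS change in high than in low clones, relative to other genes, and not a fall with LPS. Upward means the opposite. Shifted downward were chemokines (adjusted p = 2.07e-07, and 0.212 with an estimated correlation; 5 lower adjusted over the list alone), NF-kB feedback and regulators (1.34e-05, and 0.212 with an estimated correlation; 3) and antigen presentation and co-stimulation (9.34e-08, and 0.321 with an estimated correlation; 3). So were unfolded protein and integrated stress response (0.00139, and 0.354 with an estimated correlation), fibroblast and epithelial markers (0.0172, and 0.212) and IL-4-induced genes (0.028, and 0.212). Cell cycle (0.00204, and 0.354 with an estimated correlation) and mitochondrial respiration (0.0016, and 0.719) shifted upward. Without both arrays of clone 75, whose LPS array had the lowest SD, cell cycle (0.0552), mitochondrial respiration (0.124) and fibroblast and epithelial markers (0.0535) did not pass. Interferon-stimulated genes, chemokines, NF-kB, antigen presentation, cell cycle and the stress response list passed in 12 of 12 fits that left out an array. IL-4-induced genes passed in 7, fibroblast and epithelial markers in 8 and mitochondrial respiration in 9. IL-4-induced genes did not pass on ranks (0.0514) or with dim genes left out (0.212), nor did fibroblast and epithelial markers with dim genes left out (0.212). With the block, effectors (adjusted p = 0.0748 without and 0.0277 with it, downward), pan-macrophage identity (0.286 and 0.0451, upward) and cholesterol synthesis (0.0519 and 0.0247, upward) passed as well.

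**Figure D3:**
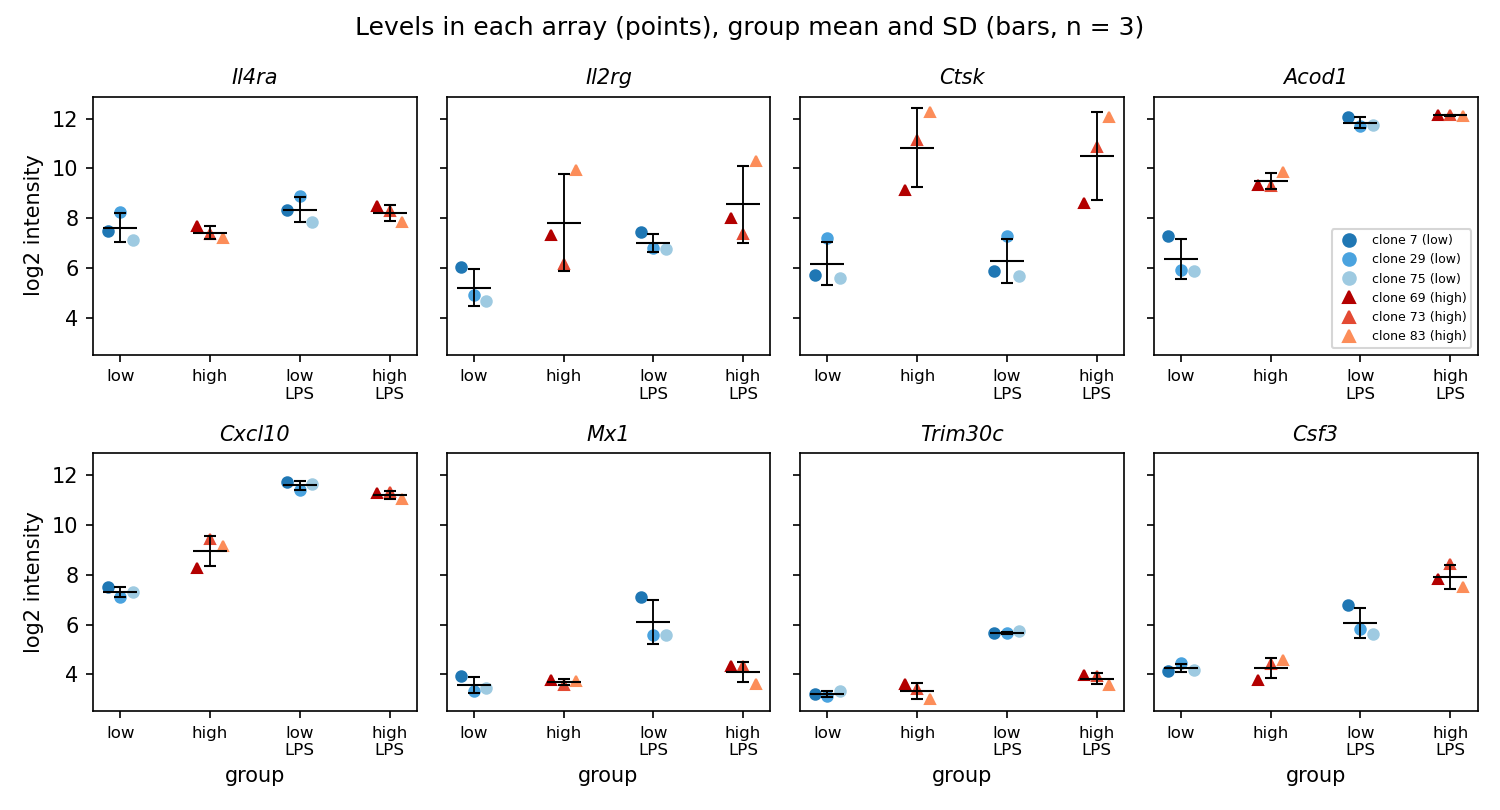
Log2 intensity of 8 genes on each array (points, shaded by clone) with the mean and SD of each group of 3 arrays. Il4ra overlapped between low and high clones, whereas Acod1 and Cxcl10 were higher in unstimulated high clones (3.13 and 1.65) and Mx1 and Trim30c lower in high clones with LPS (−2.0 and −1.84).

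Without stimulation, Ctsk, the cysteine protease cathepsin K (chromosome 3, 95499286 to 95509362), differed most between high and low clones (4.65 ± 0.86, adjusted p = 0.0229), with levels of 5.73, 7.19 and 5.61 in clones 7, 29 and 75 against 9.12, 11.12 and 12.25 in clones 69, 73 and 83. Acod1 was higher by 3.13 ± 0.30 (adjusted p = 0.00114; chromosome 14, 103046977 to 103056573), the serotonin receptor gene Htr2a by 2.64 ± 0.25 (adjusted p = 0.00114; chromosome 14, 74640840 to 74706859), Saa3 by 2.1 ± 0.34 and the beta-glucan receptor Clec7a by 1.96 ± 0.22. The histone genes H2bc4 (2.52) and H2bc8 (1.87), Cxcl10 (1.65), Tnn (1.6), the fatty acid receptor Gpr84 (1.54, chromosome 15) and Tnf (0.66 ± 0.11, adjusted p = 0.0166) were also higher. Lower were the LIF receptor Lifr (−1.97 ± 0.35, adjusted p = 0.0184), Lama3 (−1.6), H2ac1 (−1.57), Clec1a (−1.26), Ccl24 (−1.18 ± 0.26, adjusted p = 0.0498, but −0.79 and not called without clone 83), Zfp493 (−1.18), Enpp6 (−1.15), Icos (−1.15), Slc9a9 (−1.12), H2bc1 (−1.09) and, of the IL-4 receptor list, the adaptor gene Irs2 (−0.79) and Pik3r1 (−0.52), against Myc (0.74, chromosome 15).

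In this comparison 251 genes were higher and 59 lower in high clones, and 74.5% of the higher ones lay on chromosome 14 (132 genes) or 15 (55 genes), which hold 7.6% of the genes tested. The lower ones were on those chromosomes in 2 of 59 cases. When both chromosomes were left out of the test, 20 genes were higher and 7 lower, and each of these was among the 64 and 57 genes called on other chromosomes before. The counts fell to 72 and 6 without clone 29, 89 and 13 without clone 83, 129 and 19 without clone 75, 130 and 30 without clone 7 and 143 and 30 without clone 69. Without both arrays of clone 75 they were 149 and 19, and a fit of the 6 arrays alone called 48 and 5. Of 36 named genes 4 were called in all alternatives; Acod1 and Htr2a passed in 17 of 17, Clec7a in 18 of 18, and Ctsk in 8 of 18 (adjusted p = 0.0126 to 0.109), failing without any of clones 7, 29, 75, 73 or 83 (0.0839, 0.0511, 0.0835, 0.0716 and 0.0995). Ppp1r15a did not pass with the clone as a random block (0.0504). Tlr4, Il6, Il1b, Nos2, Arg1, Chil3, Stat6, Il13ra1 and Socs1 did not pass (adjusted p = 0.248 to 0.983).

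By gene list, the unfolded protein and integrated stress response list was higher in unstimulated high clones (adjusted p = 7.87e-05, and 0.833 with an estimated correlation), with 3 of 22 members called (7 adjusted over the list alone): Chac1 (0.81), Ppp1r15a (0.60) and Dnajc3 (0.58, chromosome 14). Chemokines were higher (adjusted p = 0.00774, and 0.833 with an estimated correlation) with Cxcl10, Ccl5 (1.11) and Ccl2 (0.80) called and Ccl24 lower (6 and 1 adjusted over the list alone). Effectors were higher (adjusted p = 0.00774, and 0.833 with an estimated correlation) with Acod1, Saa3, the urokinase receptor Plaur (0.85) and Gch1 (0.78, chromosome 14) called (4 adjusted over the list alone). NF-kB genes were higher (adjusted p = 0.0236, and 0.833 with an estimated correlation) with Nfkbia (0.81) and Icam1 (0.66) called (3 adjusted over the list alone), and interferon-stimulated genes (adjusted p = 0.038, and 0.912 with an estimated correlation) with Cxcl10, Rsad2 (1.28), Ifit1 (0.94) and Oasl1 (0.87) called (5 adjusted over the list alone) and a median of 0.01. On ranks, chemokines (0.138), NF-kB genes (0.138), effectors (0.106) and interferon-stimulated genes (0.389) did not pass, and with dim genes left out NF-kB (0.0803) and interferon-stimulated genes (0.102) did not. Clone 83, a high clone, had the lowest median unstimulated level of the interferon-stimulated genes (7.635). The median was 8.325 and 8.505 in the high clones 69 and 73, and 8.09, 7.93 and 7.735 in the low clones 7, 29 and 75. All 5 lists passed without the genes of chromosomes 14 and 15. The stress response list passed in 6 of 6 fits that left out an array. Chemokines failed without clone 69 (0.152), NF-kB genes without clone 75 (0.339) or 69 (0.152), effectors without clone 75 (0.113) or 69 (0.45), and interferon-stimulated genes without clone 29 (0.254), 75 (0.339), 69 (0.799) or 73 (0.854). Inflammatory cytokines, with 1 of 26 members called (adjusted p = 0.851), and the other 20 lists did not pass.

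**Figure D4:**
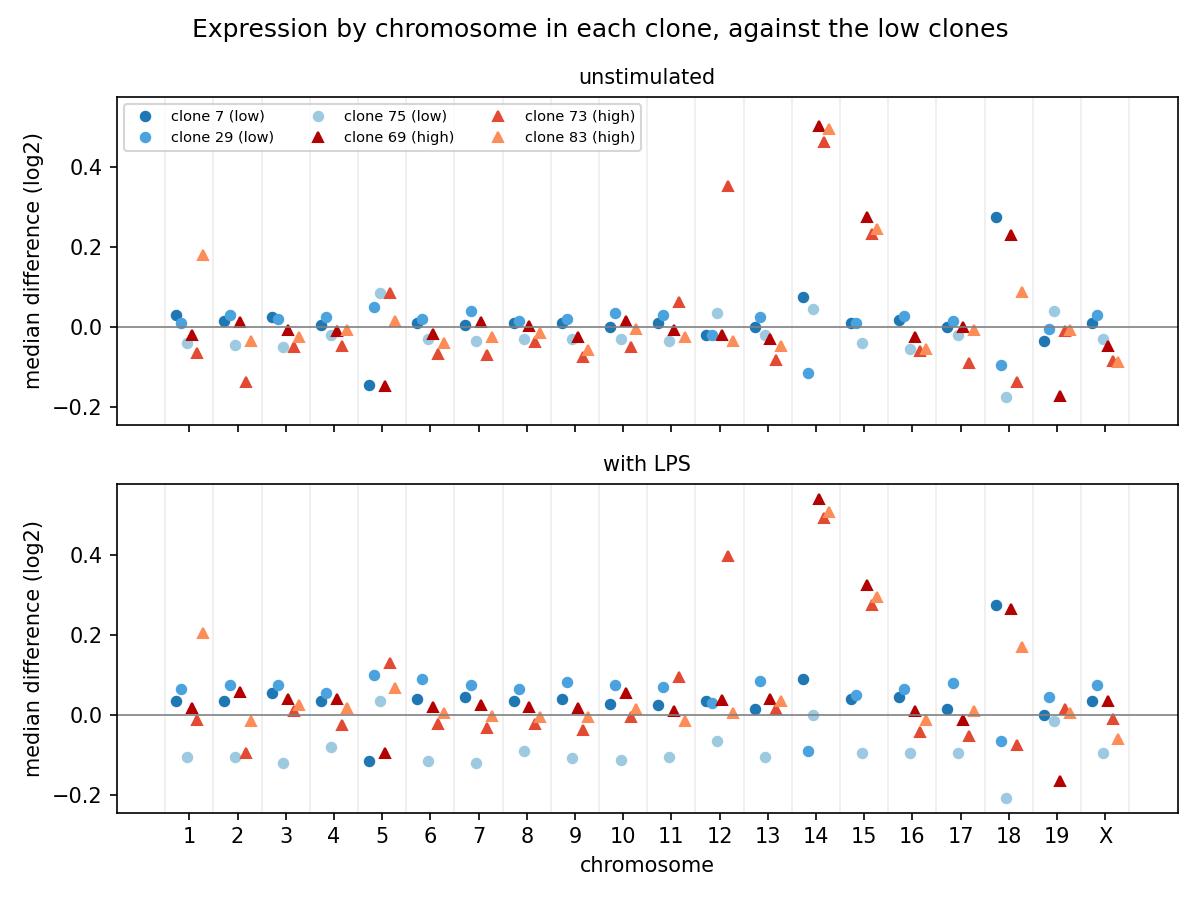
Median log2 difference of each clone from the mean of the low clones of the same condition, per chromosome, over genes with a mean log2 level of at least 6 (a low clone is set against the other 2 low clones). On chromosome 14 the high clones lie between 0.46 and 0.54 and on chromosome 15 between 0.23 and 0.32, above the low clones in both conditions.

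With LPS, several interferon-induced genes were lower in high clones. Trim30c (−1.84 ± 0.15, adjusted p = 0.000215), the GTPases Iigp1 (−1.87 ± 0.17, adjusted p = 0.000241), Mx1 (−2.0 ± 0.34), Gbp11 (−1.90) and Gbp5 (−1.75), the chemokine Cxcl11 (−2.34 ± 0.47, adjusted p = 0.0304), Ifit1bl1 (−2.28), Trim30d (−2.18), Ifi209 (−1.70) and Gdpd2 (−1.66) showed the largest differences downward. Ctsk (4.21 ± 0.86, adjusted p = 0.0329, passing in 8 of 18 alternatives with 0.0166 to 0.176), Htr2a (2.91 ± 0.25), H2bc4 (2.14), Tyrobp, a signalling adaptor of myeloid receptors (1.95 ± 0.39, adjusted p = 0.0304), the granulocyte growth factor Csf3 (1.85 ± 0.30, adjusted p = 0.00985), Id3 (1.73), H2bc8 (1.50), Btg2 (1.28, and 0.82 without clone 75), Smad9 (1.26) and the formyl peptide receptor Fpr1 (1.25) were higher in high clones. The list of interferon-stimulated genes was lower (adjusted p = 1.04e-16, and 0.505 with an estimated correlation), with a median of −0.52 and 5 of 40 members called (13 lower adjusted over the list alone), among them Mx1, Gbp5, Gbp2 (−1.39) and Isg20 (−1.11). Antigen presentation and co-stimulation was lower (adjusted p = 8.1e-08, and 0.505 with an estimated correlation) with 3 of 22 called, namely Tap1 (−1.19), Cd274, the PD-1 ligand (−0.87), and the immunoproteasome subunit Psmb10 (−0.81), and with 9 lower and 1 higher adjusted over the list alone. Of single members of other lists, Il15 (−1.10), Cxcl3 (−0.98), Cxcl9 (−0.66) and Atp6v0d2 (−1.52) were lower and Clec7a (1.02), Plaur (0.83), Egln3 (1.03) and Tab1 (0.53, chromosome 15) higher. Cholesterol synthesis and uptake was higher (adjusted p = 0.000477, and 0.505 with an estimated correlation; 0 members called, 3 adjusted over the list alone), as was mitochondrial respiration (adjusted p = 0.0413, and 0.649 with an estimated correlation; 0 called). Mitochondrial respiration failed without clone 75 (0.514) or 83 (0.411) with dim genes left out (0.142) and after quantile normalization was applied again (0.273), and the other 3 lists passed in 6 of 6 fits that left out an array. All 4 passed without the genes of chromosomes 14 and 15. Chemokines and NF-kB genes did not pass (adjusted p = 0.0791 each), but passed, downward, after quantile normalization was applied again (0.0275 and 0.018), without clone 75 (0.0417 and 0.0276) or 69 (0.0185 and 0.017) and, for chemokines, without clone 73 (0.0124).

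In all, 268 genes were higher and 91 lower in high clones with LPS. On chromosomes 14 and 15 lay 79.5% of the higher genes (158 and 55) and 1 of the 91 lower ones, and without these chromosomes 17 were higher and 38 lower. Calls shared with the unstimulated comparison, which used other arrays of the same clones, were 155 higher and 11 lower. A difference between single clones would recur in both conditions, so these counts are not independent of each other. The counts were 152 and 54 without clone 7, 136 and 50 without clone 29, 157 and 51 without clone 75, 137 higher without clone 69, 117 and 44 without clone 73 and 113 and 37 without clone 83. Without both arrays of clone 75 they were 127 and 42, and a fit of the 6 arrays alone called 89 and 38. Of 33 named genes 7 passed in all alternatives. Ctsk failed without any of clones 7, 29, 75, 73 or 83 (0.111, 0.0512, 0.14, 0.116 and 0.136), and Fpr1 did not pass with the clone as a random block (0.0618). Tlr4, Tnf, Il6, Il1b, Nos2, Arg1, Chil3, Stat6, Il13ra1 and Socs1 did not pass (adjusted p = 0.594 to 0.959).

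On the mean of both conditions, high clones differed from low clones in genes of both sets above. Ctsk (4.43 ± 0.75, adjusted p = 0.0313, passing in 8 of 17 alternatives with 0.00164 to 0.211), Htr2a (2.77 ± 0.22, adjusted p = 0.0101), H2bc4 (2.33), Acod1 (1.71), H2bc8 (1.69), the inhibitor of DNA binding Id3 (1.61), Clec7a (1.49), Kctd12 (1.19) and Scara3 (1.17), both on chromosome 14, and Serpinb8 (1.14) were higher. Lifr (−1.38), Zfp11 (−1.32), Gdpd2 (−1.29 ± 0.11, adjusted p = 0.0101), Lama3 (−1.20), Ifit1bl1 (−1.18), Clec1a (−1.13), Iigp1 (−1.11), Ccl24 (−1.03), Olfr56 (−0.99) and Spic, a factor of red pulp macrophages (−0.96), were lower. Il4ra did not pass (−0.16 ± 0.25, adjusted p = 0.897) and was 0.13 without clone 29. Il2rg did not pass (2.08 ± 0.72, adjusted p = 0.295, and 1.11 without clone 83), nor did the other fixed genes (adjusted p = 0.258 to 0.963). In total 286 genes were higher and 61 lower, 80.8% of the higher ones on chromosome 14 (168) or 15 (63), and without these chromosomes 5 were higher and 6 lower. With the clone as a random block over all arrays 530 were higher and 187 lower. The counts were 0 and 0 without clone 29 and 0 and 0 without clone 75 (limma; 2480 and 2702 genes had an unadjusted p under 0.05), 90 and 15 without clone 7, 174 higher without clone 69, 162 and 39 without clone 73 and 93 and 20 without clone 83; 3056 genes had an unadjusted p under 0.05 with all clones. None (0) of the 27 named genes passed in all alternatives.

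The lists of unfolded protein and integrated stress response (adjusted p = 0.00636; 2 of 22 called, 6 adjusted over the list alone), cholesterol synthesis (0.00636; 0 called, 2 adjusted over the list alone), effectors (0.0193; Acod1, Gch1 and Plaur called) and scavenger and phagocytic receptors (0.0193; Clec7a called) were higher on the mean, and interferon-stimulated genes (0.00504; 0 called, 2 higher and 3 lower adjusted over the list alone) and antigen presentation (0.00504; 1 lower) were lower. All 6 had adjusted p = 0.884 with an estimated correlation, and all 6 failed without at least 1 clone. Interferon-stimulated genes failed without clone 7 (0.16) or 83 (0.956, where the direction turned), antigen presentation without clone 7 (0.165) or 83 (0.105), effectors without clone 29 (0.142), 75 (0.229) or 69 (0.805), cholesterol synthesis without clone 69 (0.457) or 83 (0.0502), and the stress response and scavenger lists without clone 75 (0.101 and 0.12) or 69 (0.161 and 0.355). Effectors (0.0515) and scavenger receptors (0.0506) also failed after quantile normalization was applied again, and on ranks effectors and the stress response list failed (0.0739 each). In 33 of the 182 list tests the median, the mean and the test differed in sign, and 0 of these 33 passed. They were IL-4-induced genes over all clones, monocyte, lymphocyte and cell cycle lists in high clones, 10 lists in unstimulated clones, 4 with LPS, 8 for the difference of responses and 7 for the mean.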

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

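Leaving out single arrays, other scalings and leaving out clone 75 for the lists, and the splits of the clones, were chosen only after the results were seen, whereas the tests of the 3 explanations for the interferon-stimulated genes were written before their values were known.

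The test of the difference between the LPS responses of high and low clones singled out 3 genes, all with a smaller rise in high clones: LOC630751 (−2.42), Gm12250 (−2.12) and Trim30c (−1.97). These were the calls of limma, with 1290 genes at an unadjusted p under 0.05. Without the unstimulated array of clone 7 or of clone 83 there were 5 lower genes, and without the LPS array of clone 83 there were 5 lower and 1 higher. Of the 10 splits of the clones 1, the real one, gave as many as 3 genes, with 1 gene as the highest of the others, and 10 splits are too few for a share under 0.05.

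The same test singled out 9 gene lists by camera. Chemokines (adjusted p = 2.07e-07, from 7.34e-09 to 0.212 over the alternatives), NF-kB feedback and regulators (1.34e-05, from 3.87e-07 to 0.212), antigen presentation and co-stimulation (9.34e-08, from 2.12e-11 to 0.321), unfolded protein and integrated stress response (0.00139, from 5.25e-05 to 0.354), fibroblast and epithelial markers (0.0172, from 0.0024 to 0.212) and IL-4-induced genes (0.028, from 0.00579 to 0.212) shifted downward in high clones. Cell cycle (0.00204, from 3.07e-05 to 0.354) and mitochondrial respiration (0.0016, from 3.22e-05 to 0.719) shifted upward. For these 8 lists the highest value was that with an estimated correlation, and what led to the differences was not tested.

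Interferon-stimulated genes rose less with LPS in high clones (adjusted p = 2.62e-24, from 1.68e-49 to 0.212 with an estimated correlation), in 40 of 40 members. A single clone as the source is argued against, since the median difference of responses stayed at −0.58 or further from 0 whichever clone was left out. A higher unstimulated level with a shared ceiling is argued against for the list as a whole, because with LPS its genes were lower in high clones by a median of −0.52, with 38 of 40 below 0, but it stays open for single members such as Rsad2 (1.28 higher unstimulated and −0.21 with LPS). A weaker response of the high clones in general may account for part of the pattern. The other 3355 LPS-responsive genes followed a line with slope 0.744, and the listed genes lay below it by a median of −0.24. That value lies between the bounds of −0.1 and −0.3 set for and against this explanation. Interferon-induced genes outside the list, such as Cxcl11, are among the 3355, and how far they move the slope was not tested. The line therefore does not measure a general response alone, and this explanation stays open. The phenotype of the clones, which the design names, also stays open as an untested biological explanation.

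Features that the gene comparisons did not use also passed in the comparison of LPS with unstimulated arrays over all clones. Of 4499 features without a gene symbol 47 were higher and 74 lower, and of 5331 intron control features 53 were higher and 103 lower, adjusted over all 41345 features.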

How the results depend on the processing

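Leaving out both arrays of clone 75, leaving out chromosomes 14 and 15, the methods' t-test and, for the lists, leaving out single arrays and other scalings were chosen only after the results were seen. Counts are given as higher and lower, in this order, and where a value below differs from the report the cause was not tested, apart from fewer genes or arrays where the alternative removes them. In simulated data of the same size, with independent noise on each array, a log2 change of 0.5 was recovered for 7.46% to 61.2% of changed genes. The share depended on the comparison. The contrast of exon over intron features was 0.904 to 0.915, and how far it limits the calls was not tested. With quantile normalization applied again, median centring, the mean of a gene's features or the variance trend, all 14 counts of called genes stayed within 1.5 times the reported ones. The series matrix table holds the same values (largest difference 0), and a fit of the compared groups alone is the same fit where all groups are compared, so these tested nothing and are not counted below.

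Of the 380 reported log2 changes of named genes, tried in 7165 combinations with an alternative, 6036 values kept direction and side of the threshold, 1095 kept the direction but no longer passed, 22 passed although the reported one did not, and 12 changed sign. Of the 1095, 560 came from leaving out 1 array or clone, 130 from asking for a log2 change of at least 1, 109 from leaving out clone 75, 101 from testing all features, 80 from a fit of the compared groups alone and 51 from leaving out chromosomes 14 and 15. Among the 22 are the results of Acod1, Cxcl11, Ifit1, Rsad2 and Ifih1 for the difference of responses, which were named because they passed with the block. Another 46 results, each a gene in a comparison, were reported by an adjusted p alone, and their 845 values stayed on the same side. Their sign was not followed, a choice made after the values were seen; it changed in 51 values, none (0) of which passed. Called under all alternatives were 49 of 98 named genes over all clones, 46 of 85 in low clones and 35 of 75 in high clones. For high against low clones they were 4 of 36 unstimulated, 7 of 33 with LPS and 0 of 27 for the clone means (limma, with 3056 genes at an unadjusted p under 0.05). For the difference of responses they were 2 of 3. A gene with a smaller change fails the alternative of a log2 change of at least 1 by construction, which lowers these shares.

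The filter on dim genes gave 91 lower genes in unstimulated high clones, and array weights gave 90. With all features tested, high and low clones differed in 128 and 30 features unstimulated, in 172 and 52 with LPS and in 0 and 0 on the clone means (limma; lowest adjusted p = 0.0509, with 4065 features at an unadjusted p under 0.05). Asking for a log2 change of at least 1 lowered the counts by construction to 294 and 151 over all clones, 342 and 217 in low clones, 180 and 103 in high clones, 34 and 12 for high against low clones unstimulated, 31 and 31 with LPS and 22 and 13 on the clone means. A fit of the compared groups alone gave 293 and 287 in high clones, 48 and 5 unstimulated and 89 and 38 with LPS. Without both arrays of clone 75 the counts were 519 and 519 in low clones, 149 and 19 unstimulated, 127 and 42 with LPS and 0 and 0 on the clone means (limma; 2702 at an unadjusted p under 0.05). Without chromosomes 14 and 15 they were 20 and 7 unstimulated, 17 and 38 with LPS and 5 and 6 on the clone means. The methods' t-test gave 1128 and 1321 over all clones.

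With the clone as a fixed block, which uses the pairing of the arrays, the counts were 831 and 989 in high clones and 1 and 14 for the difference of responses, and with a random block they were 530 and 187 on the clone means. The fixed block brought 13 results of named genes past the threshold, those of Il4ra, Il2rg, Il13ra1, Stat6, Acod1, Cxcl11, Ifit1, Rsad2 and Ifih1 given in the report, and ended that of Acta2 in high clones. Acod1, Cxcl11, Ifit1, Rsad2 and Ifih1 were named because they passed with the block, so their part of the 13 was fixed in advance. The random block ended those of Ppp1r15a unstimulated and Fpr1 with LPS. Among lists the fixed block added alveolar macrophage identity in high clones and effectors, pan-macrophage identity and cholesterol synthesis for the difference of responses, where 4 lists then shifted upward. Gbp11 and Ifit1bl1, named in the report for other comparisons, also passed with the block for the difference of responses (0.0345 and 0.0418). For lists the block was run only in the LPS comparisons and the difference of responses, not for high against low clones. Among the results of genes and lists that the report gives and the block covered, it changed no other call.

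Leaving out 1 array gave 1262 to 1599 and 1482 to 1743 genes over all clones. In low clones the range was 629 to 825 and 679 to 1045, with 629 and 738 without the unstimulated array of clone 75 and 679 lower without that of clone 29. In high clones it was 284 to 430 and 305 to 406, with 284 and 305 without the LPS array of clone 69, 320 and 342 without that of clone 73 and 369 lower without the unstimulated array of clone 73. Unstimulated high against low clones ranged over 72 to 177 and 6 to 48, with 72 and 6 without clone 29, 89 and 13 without clone 83, 129 and 19 without clone 75, 130 and 30 without clone 7 and 143 and 30 without clone 69. With LPS the range was 113 to 157 and 37 to 67, with 152 and 54 without clone 7, 136 and 50 without clone 29, 157 and 51 without clone 75, 137 higher without clone 69, 117 and 44 without clone 73 and 113 and 37 without clone 83. The difference of responses gave 0 to 1 and 3 to 5 (limma; 1290 genes with an unadjusted p under 0.05), with 5 lower without the unstimulated array of clone 7 or 83 and 1 and 5 without the LPS array of clone 83. The clone means gave 0 to 174 and 0 to 49: 0 and 0 without clone 29 (2480 at an unadjusted p under 0.05) or 75 (2702), 90 and 15 without clone 7, 174 higher without clone 69, 162 and 39 without clone 73 and 93 and 20 without clone 83.

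The 12 changes of sign were those of Il4ra and Il2rg, in differences that did not pass. Leaving out 1 array or clone moved the difference of Il4ra between high and low clones from −0.44 to 0.12 unstimulated, from −0.39 to 0.13 with LPS and from −0.415 to 0.13 on the clone means, and its difference of responses from −0.25 to 0.32 (−0.0369 with array weights). Il2rg ranged from −1.92 to 0.025 in the difference of responses and from −0.12 to 1.82 in its LPS change in high clones. For LPS changes and their differences, leaving out 1 array breaks a pair. These ranges therefore include baseline differences between clones.

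The lists depended most on the correlation between genes: with an estimated correlation 49 of the 63 passing lists were lost. Camera then passed 5 and 0 lists over all clones (7 and 3 at an unadjusted p under 0.05), 6 and 0 in low clones (9 and 2), 3 and 0 in high clones (7 and 2), 0 and 0 unstimulated (1 and 0), 0 and 0 with LPS (0 and 0), 0 and 0 for the difference of responses (0 and 5) and 0 and 0 on the clone means (0 and 0). On ranks 8 lists were lost and 2 gained, which left 1 higher unstimulated and 2 on the clone means, and the dim filter lost 9 and gained 1, leaving 3 higher unstimulated and 1 with LPS. Quantile normalization lost 3 and gained 3, giving 1 and 4 with LPS and 2 higher on the clone means, and median centring lost 1 and gained 2. Without clone 75, 11 were lost and 6 gained, giving 2 higher unstimulated, 1 and 5 with LPS, 1 higher for the difference of responses and 1 higher on the clone means. Without chromosomes 14 and 15 none (0) were lost and 3 gained, giving 4 higher with LPS. Of the 119 list tests that did not pass, whose direction was not followed, 138 of 1733 values changed direction and 0 of these passed.

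Leaving out 1 array or clone kept all passing lists over all clones (12 of 12), 13 of 14 in low clones, 11 of 13 in high clones, 1 of 5 unstimulated, 3 of 4 with LPS, 6 of 9 for the difference of responses and 0 of 6 on the clone means. The counts ranged over 8 to 9 and 4 to 5 over all clones, 9 to 10 and 4 to 5 in low clones and 8 to 10 and 3 to 4 in high clones. Unstimulated they ranged over 1 to 6 and 0 to 1, with 2 higher without clone 75, 1 higher without clone 69 and 1 lower without clone 83. With LPS they ranged over 1 to 4 and 2 to 5, with 4 higher without clone 29, 1 and 5 without clone 75 and 5 lower without clone 69. The difference of responses ranged over 1 to 3 and 5 to 8, with 1 higher without the unstimulated array of clone 73 or the LPS array of clone 83. The clone means ranged over 0 to 5 and 0 to 2, with 1 higher without clone 75, 0 higher without clone 69 (camera; 1 at an unadjusted p under 0.05), 0 lower without clone 7 (2) and 0 lower without clone 83 (1). The direction of the interferon-stimulated genes on the clone means turned without clone 83 (adjusted p = 0.956).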

Other observations

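The bounds of the chromosome stretches and all splits of the arrays were chosen only after the results were seen. The tests on chromosomes 14 and 15 were written before their values were known, but after the calls had pointed to these chromosomes.

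Genes of chromosomes 14 and 15 were higher in the high clones, and a candidate explanation, put forward here as a hypothesis, is that these clones hold more copies of both chromosomes than the low clones. Over all expressed genes, called or not, the lowest of the 6 medians of the high clones was 0.46 on chromosome 14 (329 genes). It was 0.23 on chromosome 15 (404 genes), and both lay above the bound of 0.2 set for this explanation. The medians cover 3 clones, with and without LPS. Both chromosomes were picked by the genes called on these same arrays, so medians of this size are weak evidence. They show that the shift runs through the expressed genes of both chromosomes, and they do not test its cause. In a permutation test 0 of 10000 random sets of 733 genes from other chromosomes, matched on level, reached the observed median of 0.37 (highest 0.02). The permutation p was 1e-04, the smallest that this number of sets can give. Genes of the same level elsewhere were not shifted as much, which argues against a bias that depends on signal level alone. The p-value does not measure chance, since both chromosomes were picked from these data and the sets treat neighbouring genes as independent. DNA copy number was not measured, a loss in the low clones would give the same differences, and common descent of the high clones was not tested. The IL-4Ra phenotype, which the design names, stays open as an untested explanation, and Il4ra itself lies on chromosome 7.

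Single stretches stood apart as well, in low and high clones. On chromosome 15 the high clones were above the low clones by a median of 0.75 unstimulated and 0.71 with LPS from 100 Mb onward (33 genes), against 0.23 and 0.28 before it (371 genes). Outside chromosomes 14 and 15, windows of 20 Mb in which a clone lay beyond 0.2 in the same direction in both conditions were found on 6 chromosomes. Clone 73 was higher along chromosome 12 (0.35 and 0.40, 371 genes) and on chromosome 11 from 100 Mb (0.36 and 0.36, 230 genes), and lower on chromosome 2 from 140 Mb (−0.33 and −0.28, 250 genes). Clone 83 was higher on chromosome 1 from 100 Mb (0.37 and 0.40, 297 genes) and not before it (−0.03 and 0.01, 288 genes), and on chromosome 18 between 20 and 40 Mb (0.36 and 0.43, 81 genes). Clone 69 and clone 7, a low clone, were higher along chromosome 18 (0.23 and 0.27 in clone 69, 0.28 and 0.28 in clone 7, 242 genes). Clone 69 was lower on chromosome 19 between 40 and 60 Mb (−0.27 and −0.23, 106 genes).

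The counts of called genes were set against other splits of the arrays. For LPS over all clones, 1 of 100 splits drawn from 200, the real one, gave as many as 3395 genes, and the highest other split gave 437. Among the 32 splits that part every pair of arrays of a clone the highest other count was 19. These 32 splits respect the pairs and cannot give a share below 1 in 32. In all other splits LPS and unstimulated arrays share a group, so the LPS effect widens the spread and lowers their counts. The gap between the counts is therefore no measure of how far chance is excluded. The other comparisons allow 10 splits each, too few for a share under 0.05, and in each of them 1 split, the real one, gave as many genes. The real and highest other counts were 2109 and 0 in low clones, 1059 and 1 in high clones, 310 and 0 for high against low clones unstimulated, 359 and 0 with LPS, and 347 and 0 on the clone means.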
